A study of Homo sapiens with 6 samples.

How the data were processed

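Poly(A) RNA of SH-SY5Y cells was sequenced in 6 libraries, 3 of cells with a stable TDP-43 shRNA and 3 of cells with a control shRNA, made with a directional kit per the labels' protocols. The deposited table gives FPKM per gene and library. Per the submitters' processing notes the tools were TopHat2 2.1.0, SAMtools and Cuffdiff 2.2.1 on hg38, with no role or setting given. The gene annotation, and whether strand was used in counting, are not given in the sources used here, so overlapping and antisense genes and reads shared between near-identical copies cannot be resolved. Each library was a column of its own, and its group and number came from the sample titles. No further column of sample values was present.

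Columns summed to between 1182980 and 2449950 FPKM, because 6 very short or abundant small RNAs (SNORD3A, RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1) held 63.8% to 82.0% of each sum. SNORD3A and RN7SK were each listed at 0 in all libraries of a group and at 217308 FPKM or more in the other, so an exact 0 can be a failed estimate. For genes with a group at 0 the values per library are given, with no fold or SD. In all, 50 genes were listed at 0 in every knockdown library and at 1 FPKM or more in every control library, and 3 genes the other way round. FPKM cannot give the number of reads. Relative depth came from the commonest ratio of values under 0.3 FPKM between each library and control library 1, where genes with the same small number of fragments pile up. From 1363 to 2080 genes were compared and 91 to 444 lay within 0.01 log2 units of that ratio. No 2 libraries were copies of each other, since at most 1 non-zero value was identical in any pair.

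Values were taken as log2(FPKM + 1), which understates the change of low genes, and genes with a mean of 1 FPKM or more over the 6 libraries were tested. The knockdown was compared with the control by limma 3.58.1 in R 4.3.3, with an intensity trend and two-sided moderated tests, and p-values were adjusted by the Benjamini-Hochberg method over 13434 genes. A gene was called at an adjusted p under 0.05. The median SD of log2 values was 0.0932 within the knockdown and 0.0606 within the control. On simulated data of 13434 genes with the spread of these libraries, the test recovered 40% of 50 genes changed 1.25-fold, 82% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 8 of 164 calls (4.88%) were false. The changed genes were drawn from those above a minimum control level and were far fewer than the calls in the data. These rates need not hold for low genes.

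The lists of genes, 21 in all, were fixed before the data were examined, as were the tests and the other settings except where stated. They covered TDP-43 splicing targets, ALS and FTD genes, R-loop factors, DNA methylation and hydroxymethylation, transposable element silencing, interferon response, p53 targets, DNA damage repair, integrated and ER stress response, cell cycle, synapse and neuronal cytoskeleton, noradrenergic identity, mesenchymal markers, Schwann and glial markers, cholesterol, autophagy and lysosome, hnRNP and SR proteins, replication-dependent histones, nuclear oxidative phosphorylation, mitochondrially encoded transcripts and cytosolic ribosomal proteins. Each list with 3 or more tested genes was tested by limma's camera with a preset correlation of 0.01, adjusted over 20 lists. An estimated correlation and limma's fry were alternatives. On simulated data 0 of 20 random lists were called. The simulated genes were drawn independently and most had no change. The simulation therefore does not give the rate of false calls for lists of genes that vary together. Up to 8 members of a list also stand on another list.

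Genes were named by a rule: TARDBP, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and for each list described, up to 4 called members with the largest change. Members behind a count of 5 or fewer, and single genes that missed the threshold in their list, were named after their values were seen, as were DNMT3A, TET1 and TET3. For 6 lists no examples by that rule are given. Some genes that the rule names are not reported here, and others did not take their place.

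Alternatives were pseudocounts of 0.1 and 0.5, a minimum mean of 0.1 or 5 FPKM or none, median-of-ratios rescaling, quantile normalization, columns rescaled to equal sums, a replicate block, limma without the trend or with robust estimation, and leaving out each library. Added after seeing the data were a fit without genes at an exact 0 in any library and a rescaling to equal sums without the 6 small RNAs. Gene positions are 1-based, from GENCODE v29 on GRCh38, the assembly behind hg38, and 12626 of the tested genes (94.0%) matched by symbol. Permutation, annotation and region tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.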

Results

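The series measured messenger RNA in SH-SY5Y cells, a human neuroblastoma line used as a model of neurons that can hold neuron-like (noradrenergic) and flat, substrate-adherent (mesenchymal) cells. Cells had been infected with lentivirus carrying either a short hairpin RNA (shRNA) against TDP-43 or a control shRNA, and stable knockdown cells were selected with puromycin. TDP-43, encoded by TARDBP, is a nuclear RNA-binding protein that regulates splicing and is lost from the nucleus in most amyotrophic lateral sclerosis (ALS) and in part of frontotemporal dementia (FTD). There were 6 poly(A) libraries, 3 of the knockdown and 3 of the control. The table holds FPKM, fragments scaled to transcript length and library size, for 26372 genes, of which 13434 had a mean FPKM of 1 or more and were tested. FPKM does not state the number of reads, so absolute depth is unknown. The steps between low values put the depth of the knockdown libraries at 69.7%, 52.8% and 94.4% of the deepest library, and that of the control libraries at 100%, 95.9% and 84.2%. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

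The first question was whether the targeted gene was lower in the knockdown libraries. TARDBP (chromosome 1, 11012344 to 11026420, plus strand, GRCh38) stood at 21.9, 20.7 and 20.98 FPKM in the 3 knockdown libraries and at 50.3, 50.3 and 47.7 FPKM in the 3 control libraries. The means were 21.2 ± 0.598 and 49.5 ± 1.49 FPKM (SD, n = 3 each), so the knockdown held 0.428 times the control level. On the log2(FPKM + 1) scale TARDBP fell by 1.19 (standard error 0.045, limma adjusted p = 6.69e-08). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

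**Figure D1:**
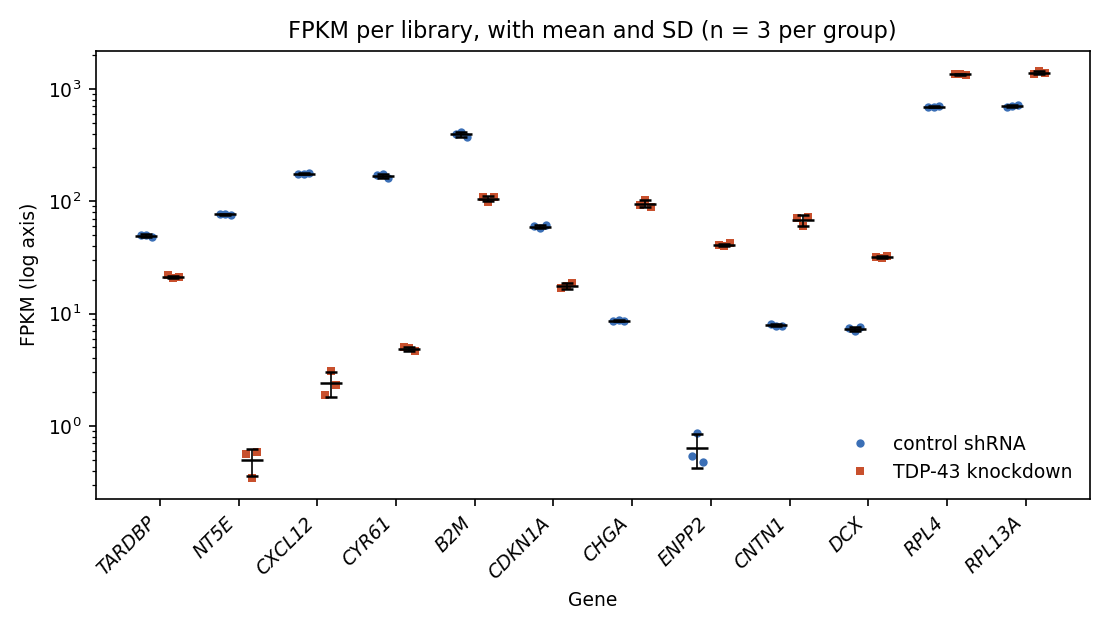
FPKM on a log axis of 12 genes in each library, with circles for the 3 control shRNA libraries, squares for the 3 TDP-43 knockdown libraries, and black bars for the mean and SD. TARDBP, NT5E, CXCL12, CYR61, B2M and CDKN1A lie lower in every knockdown library, and CHGA, ENPP2, CNTN1, DCX, RPL4 and RPL13A lie higher on the deposited scale, while with columns rescaled to equal sums the rises of RPL4 and RPL13A no longer passed the test.

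The study asked how a lasting shortage of TDP-43 changes transcription, with the title naming R-loops, 5-hydroxymethylcytosine and transposable elements. The knockdown and control libraries differed across most of the expressed genes. By limma with Benjamini-Hochberg adjustment 8909 genes (66.3% of those tested) passed an adjusted p of 0.05, 4092 higher and 4817 lower in the knockdown. A change of at least 2-fold was found for 1512 of them, 444 higher and 1068 lower. These counts depend on low genes, with 741 higher at a pseudocount of 0.1 and 244 higher at a minimum mean of 5 FPKM. The 3 knockdown values lay wholly above or below the 3 control values in 9508 genes (70.8%, against 10% by chance). Spearman correlations between libraries across tested genes, which are not independent replicates, were 0.987 to 0.995 within groups and 0.874 to 0.889 between groups. The split between higher and lower calls depends on the scaling. With columns rescaled to equal sums, the median of all genes moved by -0.75, and 523 genes were higher and 11695 lower, 4313 of them by at least 2-fold. With quantile normalization the median moved by 0.11, and 58.8% of calls were higher against 45.9% on the deposited scale. The rescaling is dominated by SNORD3A, a small nucleolar RNA listed at 1309500, 1199100 and 1533720 FPKM in the knockdown libraries and at 0 in the controls. RN7SK, a small nuclear RNA, was listed at 219330, 226681 and 217308 FPKM in the controls and at 0 in the knockdown. Very short RNAs get extreme FPKM values, so an exact 0 in this table need not mean that a gene was silent.

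Among the largest falls PRRX1 (chromosome 1, 170662728 to 170739419), a transcription factor of mesenchymal cells, stood at 68.6 ± 1.59 FPKM in the control and 0.0157 ± 0.0152 in the knockdown. The chemokine CXCL12 stood at 176.5 ± 1.51 against 2.43 ± 0.618 FPKM, the YAP-responsive gene ANKRD1 at 110.1 ± 3.31 against 0.667 ± 0.070, and the cell-surface nucleotidase NT5E at 76.6 ± 0.776 against 0.495 ± 0.133. ANXA1 was listed at 0 in the 3 knockdown libraries and at 46.2, 46.5 and 43.5 FPKM in the controls. ODAM, SULT1B1 and SULT1E1, which lie on chromosome 4 between 69721162 and 70204576, had log2 fold changes of -6.19, -5.88 and -5.50. RN7SK was also among the 10 largest falls. The limma adjusted p of these genes ran from 2.42e-16 to 1.22e-09, and the 3 libraries of either group lay apart for each.

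Among the largest rises on the log2(FPKM + 1) scale ENPP2 (chromosome 8, 119557086 to 119673453), which encodes autotaxin, stood at 41.0 ± 1.09 FPKM in the knockdown and 0.632 ± 0.211 in the control, a 64.9-fold difference of the means. CHGA (chromosome 14, 92923080 to 92935293), the chromogranin of neuroendocrine granules, stood at 95.1 ± 6.95 against 8.64 ± 0.0947 FPKM. FGFBP2, KIAA1324, DPT, NELL1, CCSER1 and DCN rose by 4.00, 3.54, 3.51, 3.36, 3.24 and 2.96 on the log2 scale. DPT and DCN encode matrix proteins. SNORD3A was also among the 10 largest rises, and the limma adjusted p of these genes ran from 6.03e-14 to 9.50e-08.

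Of 47 tested mesenchymal (substrate-adherent) markers, 42 fell and 4 rose, and 46 passed when adjusted over the list alone. Their median log2 fold change was -2.04, or -1.93 without ANXA1 and CAV1, which were listed at 0 in every knockdown library. The list was past the threshold of camera, a competitive gene set test (adjusted p = 1.81e-14), and stayed so with an estimated correlation (adjusted p = 0.00885). CTGF and CYR61, both YAP target genes, stood at 46.7 ± 1.07 and 169 ± 6.97 FPKM in the control against 0.0914 ± 0.0665 and 4.88 ± 0.216 in the knockdown. The 4 that rose, named after their values were seen, were DCN, TWIST1, LUM and IGFBP3. TWIST1, a transcription factor also active in neural crest, stood at 294 ± 7.94 FPKM in the knockdown and 110.8 ± 3.27 in the control, and LUM and IGFBP3 rose by 0.49 and 0.36 but turned negative with columns rescaled to equal sums. SNAI2 was the member that did not pass (10.4 ± 0.837 against 10.7 ± 0.240 FPKM), and it passed with columns rescaled to equal sums (-0.82). The labels give each arm a single name and no further line, so every group below was compared between libraries that also differed in these markers.

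Noradrenergic identity genes moved the other way, though not as a block. Of 35 tested, 25 rose and 7 fell, with 32 passing when adjusted over the list alone and a median of 0.72. That median was -0.18 with columns rescaled to equal sums, which is 0.59 above the median of all genes under that scaling. Camera called the list (adjusted p = 9.64e-06), and the call was lost with an estimated correlation (adjusted p = 0.085). CHGA, given above, had the largest rise of the list. INSM2 stood at 8.78 ± 0.313 against 0.602 ± 0.166 FPKM. SCG2, a granule protein gene, went the other way, from 436 ± 2.81 FPKM in the control to 38.1 ± 1.03 in the knockdown. Among 56 synapse and neuronal cytoskeleton genes 40 rose and 15 fell, 55 passed when adjusted over the list alone, and the median was 0.60. It was -0.24 with columns rescaled to equal sums, 0.53 above the median of all genes there. Camera's adjusted p was 5.29e-05, and with an estimated correlation the adjusted p was 0.085. The adhesion molecule CNTN1 stood at 68.1 ± 7.23 against 7.90 ± 0.208 FPKM and DCX, a microtubule protein of young neurons, at 32.1 ± 0.634 against 7.36 ± 0.286. CNTNAP2, at 4.03 ± 0.578 against 51.9 ± 1.30 FPKM, and the growth cone gene GAP43, at 7.29 ± 0.660 against 44.3 ± 1.97, fell. DLG4, the member that did not pass, stood at 12.25 ± 0.856 against 12.24 ± 0.717 FPKM. Only 4 of 16 Schwann and glial markers were tested. Of these 3 rose and 1 fell. NGFR and S100B rose by 1.36 and 0.61 and PMP22 fell by 0.42, S100B no longer passing with columns rescaled to equal sums. All 4 passed when adjusted over the list alone, the median was 0.99, and camera did not call the list (adjusted p = 0.2, and 0.33 with an estimated correlation). The median rests on the filter and was 0.070 at a minimum mean of 0.1 FPKM and 0.037 with no filter. With columns rescaled to equal sums it was called higher (median 0.30, adjusted p = 1.74e-04, with 0.381 the highest over camera's alternatives).

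**Figure D2:**
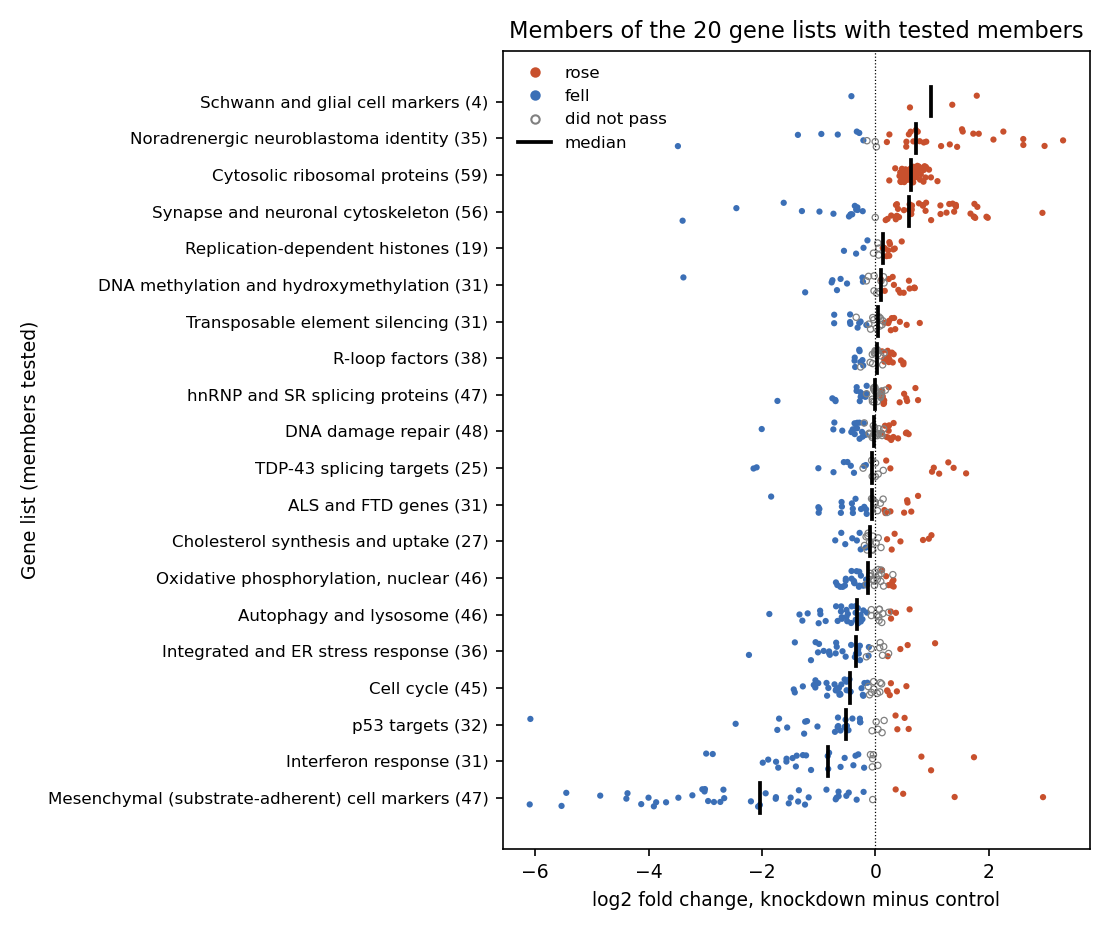
Log2 fold change, knockdown minus control on log2(FPKM + 1), of each tested member of 20 gene lists, with red points for genes that rose, blue for genes that fell, open points for genes that did not pass the adjusted p of 0.05, and a black bar for the median. The 59 ribosomal protein genes all lie above 0 and 42 of 47 mesenchymal markers fell, while with columns rescaled to equal sums the medians of the ribosomal, noradrenergic and synapse lists turned negative (-0.27, -0.18 and -0.24), and the points of ANXA1 and CAV1 depend on the pseudocount.

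All 59 genes of the cytosolic ribosomal protein list, which does not hold every such gene, rose, also when adjusted over the list alone, with a median of 0.63 and a range of 0.25 to 1.10. The median was 0.24 with quantile normalization and -0.27 with columns rescaled to equal sums, which is 0.15 and 0.49 above the median of all genes under those scalings. Camera's adjusted p was 1.28e-22, and 0.00885 with an estimated correlation. RPL13A stood at 1395 ± 43.3 against 704.5 ± 10.6 FPKM, and RPL4 at 1345 ± 18.5 against 696 ± 4.29. RPL28 had the largest rise (1.10), with 581 FPKM in knockdown library 2 and 377 and 354 in the others. With columns rescaled to equal sums RPL28, RPL13A and RPL4 no longer passed. Ribosomal protein genes have many near-identical processed pseudogenes, so their levels are uncertain where reads were shared.

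Genes of antigen presentation led the falls in the interferon response list, of which 23 of 31 tested members fell and 3 rose (26 when adjusted over the list alone, median -0.83). HLA-C, a class I histocompatibility gene, stood at 4.34 ± 0.513 FPKM in the knockdown and 41.2 ± 3.13 in the control, and its partner B2M at 105.7 ± 5.77 against 394 ± 18.05. PSMB8, an immunoproteasome subunit, stood at 0.260 ± 0.225 against 8.11 ± 0.785 FPKM, and the peptide transporter TAP1 at 0.176 ± 0.0775 against 3.65 ± 0.259. BST2, IFITM3 and IFIT3 rose by 1.74, 0.99 and 0.82, and IFITM3 no longer passed with columns rescaled to equal sums. Camera's adjusted p was 2.18e-04. The call was lost with an estimated correlation (adjusted p = 0.0668), with a minimum mean FPKM of 5 (adjusted p = 0.0728), and with columns rescaled to equal sums (adjusted p = 0.179). The estimated correlation of this list was -0.0084, under the preset of 0.01, so a higher correlation does not explain the first of these losses. The autophagy and lysosome list, at 0.0050, lost its call in the same way. For the mesenchymal list, at 0.0037, camera's adjusted p also rose, from 1.81e-14 to 0.00885. Over camera's alternatives the adjusted p of the interferon list ran from 1.79e-05 to 0.179. The median of the interferon list was -0.40 with no filter and -0.32 at a minimum mean of 5 FPKM.

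Cell cycle genes were mostly lower, with 30 of 45 fallen and 6 risen (36 when adjusted over the list alone, median -0.45, camera adjusted p = 7.79e-04, adjusted p = 0.189 with an estimated correlation). CCND1, cyclin D1, stood at 74.1 ± 2.78 FPKM in the knockdown and 202 ± 2.49 in the control. CCNA2, CDC20 and CDK1, which act in S phase and mitosis, had log2 fold changes of -1.42, -1.28 and -1.08. Genes whose symbols open with MCM, several of them on this list, were looked at after their values were seen. Of 11 tested, 6 rose and 0 fell on the deposited scale (median 0.21). Camera, adjusted over 168 such symbol families, did not call them (adjusted p = 0.125). Of 32 p53 targets 23 fell and 4 rose (27 when adjusted over the list alone, median -0.52, camera adjusted p = 0.00128, adjusted p = 0.216 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at 17.7 ± 0.986 against 59.6 ± 1.90 FPKM, GDF15 at 1.78 ± 0.496 against 14.2 ± 1.00 and FAS at 0.291 ± 0.0901 against 3.30 ± 0.613. BBC3, BTG2, CCNG2 and TP53INP1 rose by 0.39, 0.59, 0.36 and 0.52, and all 4 turned negative with columns rescaled to equal sums.

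In the integrated and endoplasmic reticulum (ER) stress list 25 of 36 fell and 4 rose (30 when adjusted over the list alone, median -0.33, camera adjusted p = 0.00259, adjusted p = 0.189 with an estimated correlation). The ER chaperone HSPA5 stood at 54.3 ± 0.303 FPKM in the knockdown and 120.3 ± 1.24 in the control, and EDEM1 and CEBPB had log2 fold changes of -2.23 and -1.42. DDIT4, an inhibitor of mTORC1 signalling, rose by 1.06. ASNS, CHAC1 and PHGDH rose by 0.22, 0.57 and 0.44 and turned negative with columns rescaled to equal sums. Of 46 autophagy and lysosome genes 32 fell and 4 rose (38 when adjusted over the list alone, median -0.33, camera adjusted p = 0.00315, adjusted p = 0.085 with an estimated correlation). The lysosomal genes NPC2 and CTSB stood at 36.0 ± 2.30 and 27.6 ± 0.385 FPKM against 134 ± 3.34 and 71.2 ± 1.82 in the control. TFE3, a transcription factor of lysosomal genes, fell by 1.19. The autophagy genes ATG14, ULK1 and ULK2 and the kinase gene MTOR rose by 0.61, 0.37, 0.28 and 0.27, and all turned negative with columns rescaled to equal sums.

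Genes tied to TDP-43 by earlier work moved in both directions. Of 25 tested genes whose splicing is known to depend on TDP-43, 8 rose and 10 fell (18 when adjusted over the list alone, median -0.053, camera adjusted p = 0.989). PFKP stood at 16.2 ± 0.514 FPKM in the knockdown and 75.0 ± 3.13 in the control and RCAN1 at 5.99 ± 0.794 against 28.7 ± 0.869. ACTL6B stood at 7.18 ± 1.15 against 2.12 ± 0.319 FPKM. Gene-level FPKM does not show splicing. Of 31 ALS and FTD genes 8 rose and 15 fell (24 when adjusted over the list alone, median -0.064, camera adjusted p = 0.691). OPTN, an autophagy receptor, stood at 2.92 ± 0.167 against 13.0 ± 0.274 FPKM, and the actin-binding gene PFN1 stood at 204.7 ± 20.1 against 410 ± 9.07. SQSTM1 stood at 23.4 ± 0.385 against 47.9 ± 3.94 FPKM, and ANXA11 fell by 0.99. The median of either list was above 0 with quantile normalization (0.030 and 0.14). Fry, which tests a list by itself and not against other genes, called both downward (adjusted p = 3.3e-04 and 8.8e-06).

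For the mechanisms in the study's title, the gene groups gave no shift that camera called. Among 38 R-loop factors 14 rose and 8 fell (22 when adjusted over the list alone, median 0.038, camera adjusted p = 0.212), none by 2-fold. THOC5, RECQL5 and TOP3B rose by 0.50, 0.50 and 0.46, each turning negative with columns rescaled to equal sums, and BRCA2 fell by 0.36. With quantile normalization camera called this list higher (median 0.25, adjusted p = 0.00469, with 0.597 the highest over camera's alternatives). Fry called the R-loop list upward (adjusted p = 0.018) and did not call the transposable element list (adjusted p = 0.0774). Of 31 genes of DNA methylation and hydroxymethylation 13 rose and 9 fell (22 when adjusted over the list alone, camera adjusted p = 0.458). The median of that list was 0.10 and its mean -0.078, camera ranked it upward and fry, a test of the list by itself, downward (adjusted p = 0.0315). Its largest changes were in GADD45B, at 0.518 ± 0.114 against 14.8 ± 0.878 FPKM, and GADD45A, at 14.03 ± 0.504 against 34.4 ± 1.29, stress-induced genes that also act in DNA demethylation. CXXC5 and ZBTB38 had log2 fold changes of -0.77 and -0.76. Of the 13 that rose, DNMT3A, a DNA methyltransferase gene, and TET1 and TET3, whose products oxidise 5-methylcytosine, were picked after their values were seen. They stood at 53.2 ± 1.03, 15.5 ± 0.415 and 15.05 ± 0.637 FPKM against 32.4 ± 0.821, 9.24 ± 0.133 and 9.62 ± 0.0945, and all 3 turned negative with columns rescaled to equal sums. Of 31 genes that silence or restrict transposable elements 10 rose and 9 fell (19 when adjusted over the list alone, median 0.0465, mean -0.0044, camera upward with adjusted p = 0.488). That median ran from 0.0018 without knockdown replicate 1 to 0.070 without knockdown replicate 2. SETDB1 and EHMT2, both histone H3 lysine methyltransferase genes, stood at 36.8 ± 0.314 and 26.5 ± 1.04 FPKM against 20.9 ± 0.348 and 17.7 ± 0.909, and both turned negative with columns rescaled to equal sums. MOV10 and APOBEC3C each fell by 0.72. The medians of these 3 lists were -0.77, -0.77 and -0.83 with columns rescaled to equal sums, close to the median of all genes there (-0.76). R-loops, 5-hydroxymethylcytosine and RNA of the elements themselves were not analysed here.

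The remaining lists were not called by camera. Of 48 DNA repair genes 13 rose and 18 fell (31 when adjusted over the list alone, median -0.025, camera adjusted p = 0.989). Of 47 hnRNP and SR splicing proteins 15 rose and 14 fell (29 when adjusted over the list alone, median -0.00095, camera upward with adjusted p = 0.592). With quantile normalization camera called the splicing proteins higher (adjusted p = 8.76e-04, with 0.806 the highest over its alternatives). Of 46 nuclear genes of oxidative phosphorylation 7 rose and 22 fell (29 when adjusted over the list alone, median -0.12, camera adjusted p = 0.2). With columns rescaled to equal sums camera called it lower (adjusted p = 0.0102, with 0.484 the highest over its alternatives). Of 27 cholesterol genes 7 rose and 8 fell (14 when adjusted over the list alone, median -0.099, mean 9.7e-07, camera downward with adjusted p = 0.989). The medians of these 4 lists were above 0 with quantile normalization (0.076, 0.27, 0.096 and 0.035), and those of DNA repair and splicing proteins also with median-of-ratios rescaling (0.00089 and 0.027). The median of the splicing proteins was also above 0 with each library left out in turn, at 0.0071 to 0.030. Of 19 replication-dependent histones 11 rose and 4 fell (15 when adjusted over the list alone, camera adjusted p = 0.144), with a median of 0.14 that was -0.76 with columns rescaled to equal sums. The 4 that fell were HIST4H4, HIST1H2BJ, HIST1H2BD and HIST1H3D, with log2 fold changes of -0.55, -0.34, -0.21 and -0.14. HIST1H3D rose by 0.18 with quantile normalization and did not pass without control replicate 3 or without the intensity trend, and HIST1H2BJ did not pass with quantile normalization. Histone genes are near-identical copies and mostly lack poly(A) tails, so their levels are uncertain in poly(A) libraries. Without knockdown replicate 2 camera called the histone list (adjusted p = 0.0476, with 0.33 the highest over its alternatives). None of the 15 mitochondrially encoded transcripts of the last list was in the table, and they were not analysed here.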

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

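The settings added after seeing the data were the fit without genes at an exact 0 and the rescaling without 6 small RNAs, and the other alternatives were fixed before the data were examined. TARDBP fell past the threshold under every alternative, by 0.97 to 2.01 on the log2 scale, and by 1.17 to 1.21 with each library left out in turn. The number of genes changed ran from 6652 (minimum mean of 5 FPKM, fewer genes tested) to 12218 (columns rescaled to equal sums), and from 7992 to 9140 with a library left out. A minimum mean of 5 FPKM left 970 genes changed at least 2-fold, and a pseudocount of 0.1 gave 2005. With columns rescaled to equal sums 523 genes were higher, 11695 lower and 4313 changed at least 2-fold, and 5340 of the 7868 genes called in both fits kept their direction. Leaving 6 small RNAs out of the sums gave 8922 calls, 42.3% of them higher, so those RNAs carry most of the shift.

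Of 92 named genes, 22 turned sign with columns rescaled to equal sums. The log2 fold changes became -0.38 for THOC5, -0.29 for RECQL5, -0.31 for TOP3B, -0.18 for DNMT3A, -0.14 for TET1, -0.23 for TET3, -0.083 for SETDB1, -0.30 for EHMT2, -0.29 for BBC3, -0.22 for BTG2, -0.46 for CCNG2, -0.32 for TP53INP1, -0.65 for ASNS, -0.13 for CHAC1, -0.43 for PHGDH, -0.79 for DLG4, -0.53 for IGFBP3, -0.31 for LUM, -0.14 for ATG14, -0.54 for MTOR, -0.41 for ULK1 and -0.49 for ULK2, where the median of all genes moved by -0.75. Equal sums are dominated by SNORD3A. With the 6 small RNAs left out of the sums, all 92 kept their call, and those that passed kept their direction. The same held with median-of-ratios rescaling. HIST1H3D turned to 0.18 with quantile normalization, and the cause was not tested. None of the others among these 92 that passed the test changed sign under an alternative in which it was tested. Apart from TARDBP, other genes that the texts name were not followed one by one. SNAI2 and DLG4, which did not pass, lay near 0 and changed sign under several.

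Camera called 9 lists, 2 with an estimated correlation (ribosomal and mesenchymal), and 8 to 11 under the other settings. Fry, which does not compare a list with other genes, called 16. With a library left out 9 or 10 were called. The medians of the TDP-43 target, ALS and FTD, transposable element, DNA repair, cholesterol and splicing protein lists, which camera did not call, lay near 0 and moved by over 1.5 times in some of these fits. The replicate numbers are shared by the groups, but same-numbered libraries did not deviate together (correlations of -0.018, -0.18 and -0.091), and no knockdown library correlated best with the control of its own number. With the replicate number as a block 8561 genes were called, 3894 higher and 4667 lower, and no named gene or list changed its call. Knockdown library 2 was the shallowest, at 52.8% of the deepest, and the effect of depth on low genes was not tested.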

Other observations

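Apart from the test of mRNAs with a terminal oligopyrimidine start, which was set before its result was seen, the gene groups and tests here were chosen after the result was seen. Subunits of the proteasome, the protease that degrades ubiquitin-tagged proteins, were lower in the knockdown. Of 31 tested, 28 fell and 1 rose (median -0.50, limma's camera adjusted p = 6.06e-07, and 0.034 with an estimated correlation), and the median stayed negative under each scaling. PSMD2 stood at 47.2 FPKM in the knockdown and 95.1 in the control, and the subunit that rose on the deposited scale was PSMD4, at 134 against 123. The 5 tested genes of the HOXD cluster, HOXD3, HOXD4, HOXD8, HOXD9 and HOXD10, all rose, by 0.91 to 1.88 (camera adjusted p = 2.99e-04, and 0.034 with an estimated correlation). The adjustment covers only these 2 groups, picked because they stood out. HOXD9 stood at 19.7 against 4.66 FPKM. The HOXD median stayed positive under each scaling.

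Grouping genes by the letters that open their symbols gave 168 families of 10 or more genes, of which camera called 10 with its preset correlation and 0 with an estimated one. The 2 with the lowest adjusted p were RPL, where 44 of 60 rose and 7 fell (median 0.56), and RPS, where 35 of 48 rose and 6 fell (median 0.49), at 0.0993 and 0.682 with an estimated correlation. They hold ribosomal protein genes, some outside the list in the report, with pseudogenes, paralogues and kinases. Collagen genes fell in 16 of 20 (median -1.35, adjusted p = 0.4 with an estimated correlation). Histone (HIST) genes, a wider set than the histone list, rose in 40 and fell in 5 of 61. Their median was 0.20 (camera adjusted p = 3.71e-04, and 0.682 with an estimated correlation). With columns rescaled to equal sums it was -0.70, 0.065 above the median of all genes there. Zinc finger (ZNF) genes rose in 205 and fell in 90 of 489 (median 0.14), and small nucleolar RNA host genes (SNHG) rose in 12 and fell in 2 of 17 (median 0.44). The adjusted p with an estimated correlation was 0.797 and 0.682, and both medians turned negative with columns rescaled to equal sums (-0.56 and -0.39).

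Mesenchymal genes fell (42 of 47), while 25 of 35 noradrenergic genes rose and 7 fell, a list whose adjusted p was 0.085 with an estimated correlation and whose median was -0.18 with columns rescaled to equal sums. If control cultures held admixed mesenchymal cells that the knockdown line lacks, and these cells held no noradrenergic transcripts, noradrenergic genes would rise by a shared dilution factor. Their log2 fold changes had an SD of 1.33 against a median standard error of 0.0573, and 7 fell. This argues against dilution by cells without these transcripts as the whole cause of the noradrenergic change. Mesenchymal cells that hold some of these transcripts would give factors that differ by gene, so their admixture stays open. For the mesenchymal fall itself the mixture cannot be told apart from a change of state of all cells: the abundant members LGALS1 and VIM stood at 157 and 266 FPKM against 1268 and 1118, and 10 of 47 members stood under 1 FPKM in the knockdown and above it in the control, which either would give. Of the 47 members 4 rose, among them DCN and TWIST1 at 37.5 and 294 FPKM against 3.98 and 110.8, and what raised them was not tested. The shortage of TDP-43 itself, and a difference between lines unrelated to it, may each underlie the pattern and remain untested.

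The joint rise of ribosomal protein genes (median 0.63) was weighed next. A scaling factor per library would move all genes about alike. It can turn the sign of the ribosomal median, which was -0.27 with columns rescaled to equal sums, but largely leaves its distance from other genes. That distance from the median of all genes was 0.65 in the deposited values and 0.49 with equal sums. The excess over other genes is thus not set by such a factor, while the rise itself depends on it. The 9 other protein-coding genes as short and abundant as most ribosomal protein mRNAs had a median of 0.16 (bootstrap 95% interval -1.43 to 0.31). That interval lay below the ribosomal median of 0.63, but 9 genes are too few to decide on a bias towards such transcripts. A wider set of 70 non-ribosomal genes, the nearest 5 per ribosomal gene in length and level, had a median of -0.20 (quartiles -0.44 and 0.19). Their median transcript length was 917 bases against 764.5, but their median level was 393 FPKM against 1162. These values argue against transcript length alone as the cause for genes of that level. A bias towards the most abundant short transcripts stays open as a cause. Quantile normalization left only 0.15 above all genes, but it makes the highest values of all libraries equal, so it cannot decide this. A candidate explanation is a rise of the mRNAs with a terminal oligopyrimidine start, the class that ribosomal protein mRNAs belong to: of 18 others, such as EEF2 (989 against 495 FPKM) and EEF1A1 (2793 against 1929 FPKM), 17 rose and 1 fell, with a median of 0.55 that was -0.35 with columns rescaled to equal sums, 0.42 above all genes there. With quantile normalization the median of these 18 lay 0.54 above that of all genes. What raised the mRNAs of this class, the knockdown included, and how far reads shared with pseudogenes count, was not tested.

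A scan of 5702 autosomal protein-coding genes in windows of 25 found 1 region with a median under the bound from 200 shuffles (-0.58), on chromosome 12 from 12725917 to 28581511, at -0.65, and 0 windows above the upper bound (0.38). The 24 genes there that were held out of the scan had a median of -0.59, and 17 were negative. A lower copy number in the knockdown line would lower nearly all genes, and the upper quartile of the held-out genes was 0.052, with a bootstrap 95% interval of -0.49 to 0.35. Too few genes were held out to decide, so copy number and regulation of these genes cannot be told apart. On simulated data the scan found 25 neighbours lowered by as much as this region in 15 of 20 runs, 40 neighbours lowered by 1 log2 unit in 20 of 20, and a false region in 1 of 20.

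TDP-43 loss has been linked to lower levels of genes with long introns, so the longest 10% of protein-coding genes (1182 genes, 175 kb or more) was compared with the rest. The difference of the medians was 0.0012 (bootstrap 95% interval -0.043 to 0.040), which argues against a fall of the median of the longest genes by 0.2 or more here. Intron length was not measured, and single long genes may differ from the median.

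The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Each of the other splits sets 2 libraries of a group and 1 of the other against the rest, so part of the difference between the groups remains and the rest enters the spread, and none of their counts is that of groups without a difference. The real split gave 8909 genes changed, 4092 higher, 4817 lower and 1512 changed at least 2-fold, and the highest of the other splits gave 0 for each by limma, with 33 to 99 genes at an unadjusted p under 0.05 (9333 in the real split). For each of these counts 1 of the 10 splits, the real one, gave a result as large. Camera's 9 lists were matched in 2 of the 10 splits: the highest other gave 9 and the lowest 6.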
